A study of Mus musculus with 39 samples.

How the data were processed

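RNA was measured in mouse small intestine after recombination by VilCreER, a tamoxifen-activated Cre recombinase expressed in the intestinal epithelium. Per the labels, mice received 2 intraperitoneal doses of 2 mg tamoxifen 24 hours apart. Mice with floxed Apc were sampled on day 4, and mice with floxed Apc and an inducible KrasG12D allele on day 3. RNA was isolated with the RNeasy Micro kit, libraries were made with a TruSeq RNA kit, and paired ends of 36 cycles were read on a NextSeq 500, per the labels' protocols. Apc loss activates WNT signalling, and KrasG12D adds constitutive RAS signalling. Eif4a1 and Eif4a2 encode the DEAD-box RNA helicases of the eIF4F translation initiation complex. The day of sampling went with the background, so differences between backgrounds cannot be separated from the day or from runs that followed it.

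The authors deposited 1 table of raw read counts per gene, whole numbers with no normalization, for 55421 Ensembl gene identifiers. Per the submitters' processing notes the tools were FastQC 0.11.8, Trim Galore 0.6.4, HISAT2 2.1.0 and featureCounts 1.6.4, on the GRCm38 build. The annotation release and the strand setting of the counting are not given in the sources used here. Without a strand setting, reads of a gene and of an antisense partner cannot be told apart. How the counting treated reads that map to several places is not given either. A gene with a near-identical copy is therefore called uncertain.

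The table had 39 columns of counts, of which 24 matched the description of 1 sample each and were used. The other 15 columns matched no description and were not used. The wild-type samples were not analysed here. The 24 libraries formed 6 groups of 4: floxed Apc alone, with floxed Eif4a1, and with Eif4a2 floxed per the labels (the libraries labelled Eif4a2 f/f), and the same 3 groups with KrasG12D. Groups are called Apc and Apc Kras backgrounds below, and a library is named by its group and replicate number. The labels give 15 males and 9 females, with 2 females and 2 males in the Apc Kras controls, 1 and 3 in Apc Kras Eif4a1, 3 and 1 in Apc Kras Eif4a2, and 1 and 3 in each Apc group. The labels title the replicates as separate samples, and p-values measure the spread between these samples. In the 36 pairs of replicates within groups the counts differed by more than sampling noise (chi-square per degree of freedom from 23.0 to 169), so no library was counted as a duplicate.

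Gene symbols and GRCm38 coordinates came from GENCODE M21, which named 55154 of the identifiers. Genes were filtered with filterByExpr, libraries were scaled by TMM, and each background was fitted on its 12 libraries with group and sex as terms by the robust quasi-likelihood test of edgeR 4.0.16. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Adjusted p-values given for genes are from this test unless another tool is named. The difference of an effect between backgrounds was the interaction in a fit of the 24 libraries. CPM values (counts scaled to a common library size) were computed from the deposited counts with TMM factors. Standard errors of log2 fold changes were taken from the fold change and its test statistic.

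For 36 gene lists (cell types of the intestine, pathways and translation), members that rose or fell were counted after adjustment over all genes tested, and again after adjustment over the list alone. Each list with at least 5 tested members was set against the other genes with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with a correlation estimated per list. No camera call in any of the 4 comparisons held with the estimated correlation. The fry test was run as an alternative. Groups, lists, tests and the rule for named genes were fixed before the data were examined.

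The text names genes by this rule. Eif4a1, Eif4a2, Apc and Kras come first. Then, for each comparison of a deletion with its control, come the 8 largest rises and 8 largest falls among genes past the threshold with a mean CPM of at least 2 and no overlap between the groups, leaving out predicted genes (Gm numbers, Rik), immunoglobulin and T cell receptor segments, Xist and Y-linked genes. For each list called by camera the 2 members with the smallest p are named. For differences between Eif4a1 deletion and the libraries labelled Eif4a2 f/f or between backgrounds the 5 largest per direction are named. Genes outside the rule are marked as chosen after their values were seen. Values per library of Ighm, Prss2 and Myh11 were chosen in that way too, as were Rcl1, Nop16, Fabp1 and Cd79a, named because they turned with covariates.

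The tests were tried on simulated data with 200 changed genes in 3 sets of counts drawn from the means and depths of each comparison. For Eif4a1 deletion the test recovered 12.9%, 42.3% and 81.8% of genes changed 1.5-fold, 2-fold and 4-fold in Apc, and 12.9%, 44.8% and 85.4% in Apc Kras. For the libraries labelled Eif4a2 f/f it recovered 6.47%, 37.3% and 79.8% in Apc, and 10.9%, 54.7% and 85.9% in Apc Kras. For the differences between backgrounds, 2.99%, 27.9% and 64.1% were recovered for Eif4a1. False calls made up 2.73% to 6.19% of the calls across all the comparisons. The simulated genes were drawn independently, so shifts of many genes together between samples were left out. These rates therefore do not cover such structure in the real libraries. The total count per library, 25642265 to 39668451, sets the counting error, and the number of libraries sets the rest. Counting intervals cover counting error only.

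Alternatives to these choices were: RLE and upper-quartile scaling, no filter or a mean CPM of at least 2, no sex term, the replicate number as a block, DESeq2 1.42.0, limma-voom, 1 fit of the 24 libraries, the 2 compared groups alone, and leaving out each library in turn. Added after seeing the data were fits without 2 libraries with high immunoglobulin counts, without Apc Eif4a1 replicates 1 and 2, without Apc Kras replicates 1 and 2, and with smooth muscle and B cell list levels as covariates. Members of the B cell list themselves rose with Eif4a1 deletion, so the fit with covariates can also take out part of the group difference. Copies of genes were searched with BLAST 2.17.0 among GENCODE M21 transcripts, and a gene was called uncertain when at least 50% of its transcript lay at 95% identity or more in matches of at least 72 bases, or when another gene overlapped at least 20% of its exons. R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.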

Results

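The transcriptomes of 24 small intestine libraries were compared in 6 groups of 4, to ask how loss of either eIF4A helicase alters gene expression after Apc loss, with and without KrasG12D. Total counts per library ranged from 25642265 to 39668451. Mitochondrially encoded transcripts took 3.54% to 4.64% of counts, and the 10 most abundant genes took 5.29% to 9.01%.

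Eif4a1 (ENSMUSG00000059796, GRCm38 chromosome 11, 69666936 to 69672423) fell in the libraries with floxed Eif4a1. In Apc it stood at 245 ± 34.5 CPM (SD, n = 4) against 392 ± 10.8 in the controls, a log2 fold change of -0.67 ± 0.10 (SE, edgeR adjusted p = 0.00515), and the 4 deleted libraries (208.5 to 285.0) lay below the 4 controls (380.4 to 403.6). In Apc Kras it stood at 311 ± 19.0 against 442 ± 85.2 CPM (log2 -0.51 ± 0.13, edgeR adjusted p = 0.0188). There the deleted libraries reached from 287.8 to 330.3 and the controls from 326.5 to 531.7, and the call was lost without Apc Kras replicate 3 (log2 -0.50) or replicate 4 (-0.49). Eif4a-ps4, a processed pseudogene on chromosome 1 (60703932 to 60705149) that is 99.9% identical to the Eif4a1 transcript over 1218 bases, fell as well, to 104 from 237 CPM in Apc and to 106 from 269 CPM in Apc Kras (log2 -1.17 ± 0.13 and -1.36 ± 0.14). It shares reads with Eif4a1, so both values are uncertain, and it was chosen after its values were seen.

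Eif4a2 (ENSMUSG00000022884, chromosome 16, 23107444 to 23114136), the closest paralog, rose with Eif4a1 deletion. Its log2 fold change was 0.71 ± 0.11 in Apc (433 ± 13.2 against 268 ± 38.7 CPM, edgeR adjusted p = 0.00573) and 0.85 ± 0.09 in Apc Kras (531 ± 41.2 against 297 ± 17.5 CPM, edgeR adjusted p = 0.00108). In the libraries labelled Eif4a2 f/f, Eif4a2 counts were not lower. They stood at 287 ± 17.3 against 268 ± 38.7 CPM in Apc (log2 0.12 ± 0.11, edgeR adjusted p = 0.771) and at 326 ± 15.1 against 297 ± 17.5 CPM in Apc Kras (log2 0.11 ± 0.09, edgeR adjusted p = 0.748). Whole-gene counts thus did not check these labels, and directions drawn from these libraries follow the labels. Eif4a1 in them had log2 fold changes of -0.24 in Apc and 0.01 in Apc Kras, neither past the threshold. Apc and Kras transcripts did not pass the threshold in any of the 4 comparisons with controls, with log2 values from -0.25 (Apc, with Eif4a1 deletion in Apc) to 0.20 (Kras, with Eif4a1 deletion in Apc Kras).

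Sequences close to Eif4a2 did differ in the libraries labelled Eif4a2 f/f. Gm2999, a processed pseudogene on chromosome 15 (71794570 to 71795107) that aligned to exons 8 to 11 of the Eif4a2 transcript at 93.8% identity over 451 columns, gaps included, stood at 1.41 ± 0.69 against 6.15 ± 0.58 CPM in Apc (log2 -2.10 ± 0.28, edgeR adjusted p = 0.0631) and fell to 0.971 ± 0.17 from 3.61 ± 0.43 CPM in Apc Kras (log2 -1.95 ± 0.15, edgeR adjusted p = 0.000887). Gm24616, a snoRNA in the intron between exons 9 and 10 of Eif4a2 (chromosome 16, 23111617 to 23111755), stood at 0.102 against 0.557 CPM in Apc and fell to 0.0955 from 0.518 CPM in Apc Kras (log2 -2.29 ± 0.30, edgeR adjusted p = 0.0311). Both were lower in 8 of 8 libraries labelled Eif4a2 f/f than in every control of their background, and both were chosen after their values were seen. Shorter matches to Eif4a2 transcripts, at up to 100% identity, covered 98.4% of Gm2999, so it shares reads with Eif4a2 and is uncertain.

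**Figure D1:**
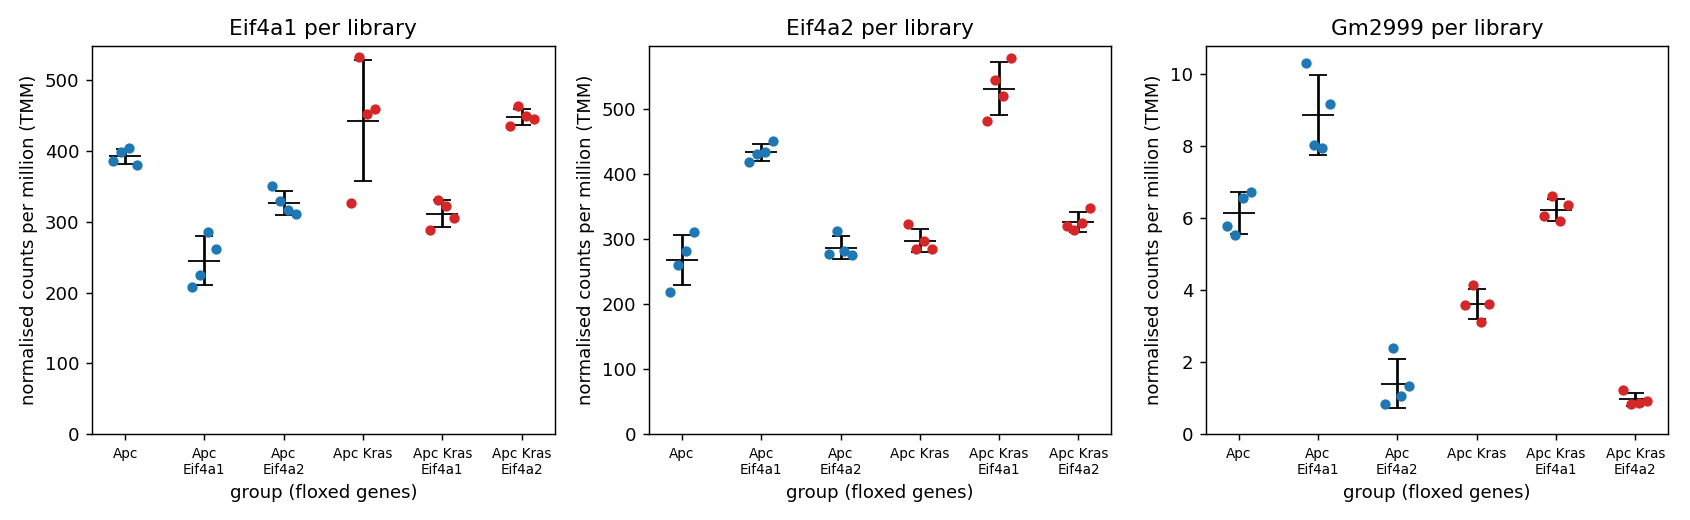
Normalised CPM of Eif4a1, Eif4a2 and the pseudogene Gm2999 in each of the 24 libraries by group, with blue points for Apc and red points for Apc Kras, and black marks for the mean and SD of 4 libraries. Eif4a1 was lower in the Eif4a1 groups (means 245 and 311), Eif4a2 was not lower in the libraries labelled Eif4a2 f/f (means 287 and 326), and Gm2999 was lower there (means 1.41 and 0.971).

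In the Apc background, genes that fell with Eif4a1 deletion included WNT targets, intestinal stem cell genes and genes of cell division and cholesterol synthesis. Lgr5, the receptor that marks crypt base stem cells, fell to 8.87 ± 3.81 from 56.6 ± 15.8 CPM (log2 -2.73 ± 0.41, edgeR adjusted p = 0.006), and Prox1, a transcription factor induced by WNT signalling in intestinal tumours, fell by 2.73 ± 0.28 on the log2 scale (edgeR adjusted p = 0.00121). The largest rise among named genes was in Tmprss15, the duodenal protease that activates trypsinogen (33.7 ± 10.8 against 1.86 ± 1.38 CPM, log2 4.20 ± 1.06), and the largest fall was in Gkn3, a gastrokine (0.302 ± 0.25 against 14.3 ± 5.25 CPM, log2 -5.53 ± 0.55). In all, 1695 of 20061 genes changed (edgeR), 769 higher and 926 lower, and 709 of them by more than 2-fold.

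Other genes with large rises were the keratin Krt12 (log2 3.93 ± 0.28), G6pc, which encodes glucose-6-phosphatase (3.28 ± 0.68), Bbox1, an enzyme of carnitine synthesis (2.67 ± 0.33), Pianp (2.34) and the lymphocyte genes Cd6 (3.00 ± 0.73), Cd3d (2.44 ± 0.64) and Lax1 (2.11 ± 0.52). Krt12 shared 54.4% of its exon sequence with an overlapping transcript and is uncertain. Large falls were seen in the water channel Aqp5 (-4.45 ± 0.99), Egfl6 (-4.09), Pla2g4c, a cytosolic phospholipase (-3.63), Prr18 (-3.55), Asb4 (-3.31), Spp1, which encodes osteopontin (-3.26 ± 0.42), and Pdgfrl (-3.04 ± 0.37). The call of Tmprss15 was lost when any single library other than Apc Eif4a1 replicate 3 was left out (log2 3.77 to 4.57).

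Of 27 WNT targets, 13 fell and none rose (16 adjusted over the list alone), among them Prox1 and Rnf43, a feedback inhibitor of WNT receptors (log2 -0.72 ± 0.10). Of 17 stem cell genes, 10 fell (11 adjusted over the list alone), including Igfbp4 (-1.30 ± 0.12) and Lgr5. Of 46 proliferation genes, 14 fell (31 adjusted over the list alone), including thymidylate synthase Tyms (-0.82 ± 0.17) and the mitotic cyclin Ccnb2 (-1.0 ± 0.23). Of 25 genes of cholesterol synthesis, 10 fell (16 adjusted over the list alone), with Acat2 (-1.12, uncertain because it shares reads with Acat3) and Mvd (-0.80 ± 0.12) leading. These 4 lists were lower than other genes by camera (adjusted p = 2.82e-07, 2.13e-07, 4.59e-13 and 2.5e-09, and adjusted p = 0.617 with an estimated correlation for each of them). The ribosomal protein list had 3 members that fell out of 79 (1 adjusted over the list alone), with Rpl3 (-0.50) and Rpl19 (-0.35) leading, both uncertain because of near-identical copies (camera adjusted p = 4.78e-05, and adjusted p = 0.617 with an estimated correlation). No member of 44 in the ribosome biogenesis list passed, over all genes or adjusted over the list alone (median log2 -0.26, camera adjusted p = 3.19e-05, and adjusted p = 0.682 with an estimated correlation). Its leading members were Gar1 (-0.51, edgeR adjusted p = 0.0508) and Fbl (-0.43, edgeR adjusted p = 0.0613). The list pointed higher without Apc Eif4a1 replicates 1 and 2, a choice made after seeing the data (camera adjusted p = 0.49).

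Of 35 enterocyte genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with the fructose-metabolising aldolase Aldob (1.22 ± 0.18) and the brush border protease Mep1b (0.83 ± 0.14) rising (camera adjusted p = 0.00217, and adjusted p = 0.617 with an estimated correlation). Of 29 genes of fatty acid oxidation and ketogenesis, 6 rose and 1 fell (11 and 2 adjusted over the list alone), including Ehhadh (0.86) and Acadm (0.65), enzymes of peroxisomal and mitochondrial beta-oxidation. Of 56 nuclear genes of oxidative phosphorylation 3 rose (2 adjusted over the list alone), with Cycs (0.72) and Sdhb (0.61) leading. Camera gave adjusted p = 0.00484 and 4.42e-07 for these lists, and adjusted p = 0.617 with an estimated correlation for both. Of 26 genes of the unfolded protein response, 5 rose (9 adjusted over the list alone), led by Derl3 (1.63 ± 0.30) and Edem1 (0.40 ± 0.09), both of which act in degradation from the endoplasmic reticulum (camera adjusted p = 0.000169, and adjusted p = 0.617 with an estimated correlation). Derl3 is also on the B and plasma cell list, members of which rose in the same comparison. The tuft cell list had 1 riser and 1 faller among 20 genes (3 and 1 adjusted over the list alone), Alox5ap (1.01 ± 0.25) and Cd24a (-0.96 ± 0.24) (camera adjusted p = 0.0138, and adjusted p = 0.617 with an estimated correlation).

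Lymphocyte genes were among those that rose. Of 22 T and NK lymphocyte genes, 10 rose (22 adjusted over the list alone), including Nkg7 (1.16 ± 0.23) and the perforin gene Prf1 (1.44 ± 0.30). Of 16 B and plasma cell genes, 7 rose (8 adjusted over the list alone), including the immunoglobulin J chain gene Jchain (1.64 ± 0.23) and Tnfrsf17 (2.00 ± 0.30). Camera returned adjusted p = 1.34e-09 and 3.26e-07 for these lists, and adjusted p = 0.617 with an estimated correlation for both. Ighm, the heavy chain gene of IgM, reached 996 CPM in Apc Eif4a1 replicate 1 and 385 CPM in Apc Eif4a2 replicate 2, against 10.9 to 13.8 CPM in the controls. Without these 2 libraries the median log2 fold change of the T and NK list moved from 1.55 to 1.08 and that of the B and plasma cell list from 2.74 to 1.67. Of 8 genes of MHC class II, H2-Aa rose (1.17 ± 0.31; 5 members adjusted over the list alone) and H2-Ab1 had a log2 value of 0.92. Of 41 interferon response genes, 4 rose (5 adjusted over the list alone), among them Psmb9 (1.23) and Nlrc5 (1.48), which act in presentation by MHC class I. The camera test gave adjusted p = 0.003 and 0.00019 for these, and adjusted p = 0.617 and adjusted p = 0.725 with an estimated correlation.

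Endothelial genes numbered 6 risers and 1 faller out of 15 (10 and 1 adjusted over the list alone), the riser Cldn5 (2.02 ± 0.43) being a tight junction gene and the faller being Prox1, which is also on the WNT list. Fibroblast genes had none of 17 past the threshold (2 adjusted over the list alone), with Dpt at 0.85 and C1s1, uncertain because of its copy C1s2, at 0.79. None of 15 genes of enteric neurons and glia passed, over all genes or adjusted over the list alone, with Plp1 at 0.76 and Sox10 at 1.39. Camera placed these 3 lists higher (adjusted p = 0.00593, 0.00102 and 0.0273, and adjusted p = 0.617, adjusted p = 0.617 and adjusted p = 0.733 with an estimated correlation). Myeloid genes, with 1 of 19 higher (none adjusted over the list alone), and smooth muscle genes, with none of 14 past either threshold, were not called (camera adjusted p = 0.424 and 0.294), nor were the other 16 of 36 lists. The call of the tuft cell list was lost without Apc Eif4a1 replicate 1 (camera adjusted p = 0.0862), and that of enteric neurons and glia without Apc replicate 4 (0.264) or Apc Eif4a1 replicate 2 (0.0955).

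The count of 1695 genes was carried by particular libraries: it was 402 without Apc replicate 3, 470 without Apc replicate 1, 948 without Apc replicate 4, 871 without Apc Eif4a1 replicate 1 and 1027 without Apc Eif4a1 replicate 2, and DESeq2 called 3170. There were 1116 with no filter, 540 with only the 2 groups compared and 3254 in 1 fit of 24 libraries. Fits chosen after seeing the data gave 889 without the 2 immunoglobulin-high libraries and 431 without Apc Eif4a1 replicates 1 and 2. With smooth muscle and B cell list levels as covariates, a choice made after seeing the data, it was 452, and 18 lists or more were called in 15 of 35 splits of the 8 libraries. Without Apc Eif4a1 replicates 1 and 2, 7 of the 18 list calls were lost and 1 list turned direction.

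In the Apc Kras background, most genes on the lists of ribosomal proteins, cell division and cholesterol synthesis fell with Eif4a1 deletion, and most on the interferon response, tuft cell, T and NK cell and myeloid lists rose. Rpl3, a protein of the large ribosomal subunit, fell by 0.99 ± 0.15 on the log2 scale (edgeR adjusted p = 0.00352). Lss, the lanosterol synthase, fell to 33.3 ± 7.71 from 88.9 ± 13.9 CPM (log2 -1.49 ± 0.14, edgeR adjusted p = 0.00108). Xaf1, an interferon-induced gene within 20 Mb of Eif4a1 on chromosome 11 (72301629 to 72313733), rose to 62.6 ± 21.8 from 10.2 ± 3.92 CPM (log2 2.78 ± 0.46, edgeR adjusted p = 0.00471), and Pck1, the gluconeogenic PEP carboxykinase, fell to 43.6 ± 4.84 from 497 ± 134 CPM (log2 -3.51 ± 0.50, edgeR adjusted p = 0.00326). In all, 5273 of 19703 genes changed (edgeR), 2555 higher and 2718 lower, and 1564 of them by more than 2-fold.

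Ccnb1ip1, a gene on chromosome 14 (50789248 to 50807732), had 1 count in the 4 controls together and 1914 in the 4 deleted libraries, a ratio of 1600 with a 95% counting interval from 287 to 63200. It was not named among the largest rises over the Apc Kras libraries labelled Eif4a2 f/f. Those rises went down to a log2 value of 3.01, for Adamtsl3. The difference from the controls alone therefore does not tie Ccnb1ip1 to the deletion, and its cause was not tested. Krt12 rose by 3.32 ± 0.52, C87414 by 2.84 ± 0.33, the monooxygenase Fmo1 by 2.67 ± 0.37, Art2b by 2.59 ± 0.39, Apol9b by 2.52 and Apol7c by 2.42. C87414, Apol9b and Apol7c have near-identical copies and are uncertain. Falls were largest in S100g, a calcium-binding protein of absorptive cells (-4.42 ± 0.58), Gkn3 (-3.43 ± 0.62), Eif4ebp3, a binding partner of eIF4E (-3.35, uncertain because of an overlapping gene), Myl7 (-3.26 ± 0.45), the metallothionein Mt2 (-2.92 ± 0.28, uncertain because of an overlapping gene), Hoga1 (-2.67 ± 0.36) and the pancreatic carboxypeptidase Cpa2 (-2.58 ± 0.64). Control library Apc Kras replicate 2 held pancreatic transcripts (Prss2 at 26.4 CPM, against at most 0.0306 CPM in the other controls). Cpa2 stood at 3.21 ± 3.30 CPM in the controls, with a highest value of 8.03. Its log2 fold change was -1.84 without Apc Kras replicate 2. The Cpa2 call was lost without Apc Kras replicate 4 (-2.58) or Apc Kras Eif4a1 replicate 2 (-2.23), and with only the 2 groups compared (-2.60). It was also lost with smooth muscle and B cell list levels as covariates, a choice made after seeing the data (-0.37).

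Of 79 ribosomal protein genes, 59 fell and none rose (70 adjusted over the list alone, median log2 -0.53). Rpl3 and Rpl36a (-0.82) led and are uncertain because of near-identical copies. Of 46 proliferation genes, 40 fell (43 adjusted over the list alone), including the spindle protein Nusap1 (-1.35 ± 0.18) and thymidine kinase Tk1 (-1.29 ± 0.19). Of 25 cholesterol synthesis genes, 22 fell (23 adjusted over the list alone), including Nsdhl (-0.84 ± 0.08) and Lss. Of 17 stem cell genes, 8 fell (10 adjusted over the list alone), including Cdca7 (-1.05 ± 0.21) and Msi1 (-1.31 ± 0.27). Testing with camera gave adjusted p = 2.25e-15, 2.25e-15, 3.74e-13 and 0.00144 for these 4 lists, and adjusted p = 0.594 with an estimated correlation for each. In the ribosome biogenesis list 5 of 44 fell (1 adjusted over the list alone), led by Polr1c (-0.54) and Gar1 (-0.48). In the translation initiation list 16 fell and 4 rose out of 44 (16 and 5 adjusted over the list alone), with Pdcd4, an inhibitor of eIF4A, at -1.35 ± 0.19 and the helicase gene Dhx29 at 0.67 ± 0.11. Camera gave adjusted p = 0.00141 and 0.0233 for these, and adjusted p = 0.753 with an estimated correlation for both. The 27 WNT targets, with 7 lower and 2 higher (7 and 3 adjusted over the list alone), were not called by camera in this background (adjusted p = 0.239).

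Of 41 interferon response genes, 27 rose and none fell (40 adjusted over the list alone, median log2 1.43), led by Ifi27 (1.29 ± 0.22) and Xaf1 (camera adjusted p = 3.99e-12, and adjusted p = 0.594 with an estimated correlation). Of 20 tuft cell genes, 11 rose (13 adjusted over the list alone), including Rgs13 (1.70 ± 0.25) and Kctd12 (1.24, uncertain because of an overlapping gene), and camera gave adjusted p = 4.45e-06, and adjusted p = 0.594 with an estimated correlation. Of 23 enteroendocrine genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with the hormone genes Cck (1.95 ± 0.37) and Gip (1.43 ± 0.27) rising (camera adjusted p = 0.00105, and adjusted p = 0.594 with an estimated correlation). Of 17 Paneth cell genes, 4 rose (none adjusted over the list alone), led by the defensin genes Defa26 (1.69) and Defa3 (1.53), which are uncertain because the family shares reads. Of 20 genes of fetal or regenerative epithelium, 3 rose (3 adjusted over the list alone), among them Cd55 (1.32 ± 0.18) and the connexin gene Gja1 (1.05 ± 0.24). Camera returned adjusted p = 0.0159 and 0.0323 for these, and adjusted p = 0.72 with an estimated correlation for both. Of 17 YAP targets, 7 rose and 2 fell (10 and 2 adjusted over the list alone), including Nuak2 (1.05 ± 0.21) and Crim1 (0.47 ± 0.10) (camera adjusted p = 0.0124, and adjusted p = 0.594 with an estimated correlation). Of 26 unfolded protein response genes, 7 rose and 1 fell (13 and 1 adjusted over the list alone), with the chaperones Hyou1 (0.55 ± 0.11) and Hspa5 (0.58 ± 0.12) rising (camera adjusted p = 0.000447, and adjusted p = 0.602 with an estimated correlation). Of 30 p53 targets, 4 rose and 1 fell (2 and 1 adjusted over the list alone), Rrm2b (0.56) rising and Ddb2 (-0.86, uncertain because of an overlapping gene) falling (camera adjusted p = 0.0371, and adjusted p = 0.72 with an estimated correlation).

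T and NK lymphocyte genes numbered 15 risers of 22 (18 adjusted over the list alone), including Cd4 (1.39 ± 0.19) and Trbc1 (1.2, uncertain because of its copy Trbc2). B and plasma cell genes numbered 6 of 15 (10 adjusted over the list alone), including Cd22 (1.53 ± 0.25) and Ighm (1.13 ± 0.26). Myeloid genes numbered 15 risers and 1 faller of 20 (16 and 1 adjusted over the list alone), including Adgre1, which encodes the macrophage antigen F4/80 (1.38 ± 0.15), and Mpeg1 (1.04 ± 0.13). The camera test gave adjusted p = 2.81e-08, 5.69e-05 and 4.44e-08 for these 3 lists, and adjusted p = 0.594 with an estimated correlation for each. MHC class II had 3 risers of 8 (5 adjusted over the list alone), with H2-DMb2 (0.83, uncertain because of its copy H2-DMb1) and H2-Eb1 (0.95 ± 0.32), and enteric neurons and glia had 3 of 15 (none adjusted over the list alone), with Phox2b (1.07) and Elavl4 (1.01). Testing with camera gave adjusted p = 0.0103 and 0.0014 for these, and adjusted p = 0.602 with an estimated correlation for both. Fibroblast genes numbered 6 of 17 (10 adjusted over the list alone), with Pdgfra (0.58 ± 0.15) and C1s1 (0.79, uncertain) rising, and endothelial genes 9 risers and 1 faller of 15 (9 and 1 adjusted over the list alone), with Tek (1.10 ± 0.21) and Flt1 (0.60 ± 0.12) rising. Camera gave adjusted p = 0.00105 and 0.00263 for these, and adjusted p = 0.594 with an estimated correlation for both. None of 14 smooth muscle genes passed, over all genes or adjusted over the list alone, and camera did not call the list (adjusted p = 0.0924).

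The control library Apc Kras replicate 1 stood apart across genes, with chi-square per degree of freedom of 92.42 to 169.31 against the other controls. Among those others it was 26.21 to 64.46. In replicate 1, Eif4a1 (326.5 CPM) and Lgr5 (14.75 CPM) lay within the ranges of the deleted libraries (287.8 to 330.3 and 7.389 to 14.82 CPM). Olfm4 (1375 CPM) and Nlrp1b (13.94 CPM) lay above theirs (at most 1000 and 1.747 CPM). Whether it resembled the deleted libraries as a whole was not tested. In single genes it had lower Rpl3 (152 against 252 to 271 CPM) and higher Ifi27 (34.5 against at most 22.4 CPM) than the other controls. Rpl34 (105.6 CPM) lay among them there (102.5 to 112.8 CPM). Without it the count of changed genes was 8739, without replicate 3 it was 2405, without replicate 4 it was 2055, and without Apc Kras Eif4a1 replicates 2, 3 or 4 it was 2876, 3314 or 3438, and with only the 2 groups compared it was 3380. List calls were lost without Apc Kras replicate 1 for fetal or regenerative epithelium and p53 targets (camera adjusted p = 0.223 and 0.174) and without replicate 2 for translation initiation (0.176). The same held without replicate 3 for Paneth cells, fetal or regenerative epithelium and p53 targets (0.0576, 0.0559 and 0.0793). They were also lost without Apc Kras Eif4a1 replicate 2 for fetal or regenerative epithelium and p53 targets (0.207 for both) and without replicate 4 for Paneth cells, fetal or regenerative epithelium and p53 targets (0.126, 0.0789 and 0.0564). With smooth muscle and B cell list levels as covariates, a choice made after seeing the data, 22 genes were called. The B cell list was higher in the deleted libraries, so that count does not tell cell composition from an effect of the deletion. In 11 of 35 splits of the libraries as many lists were called as the real 21.

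**Figure D2:**
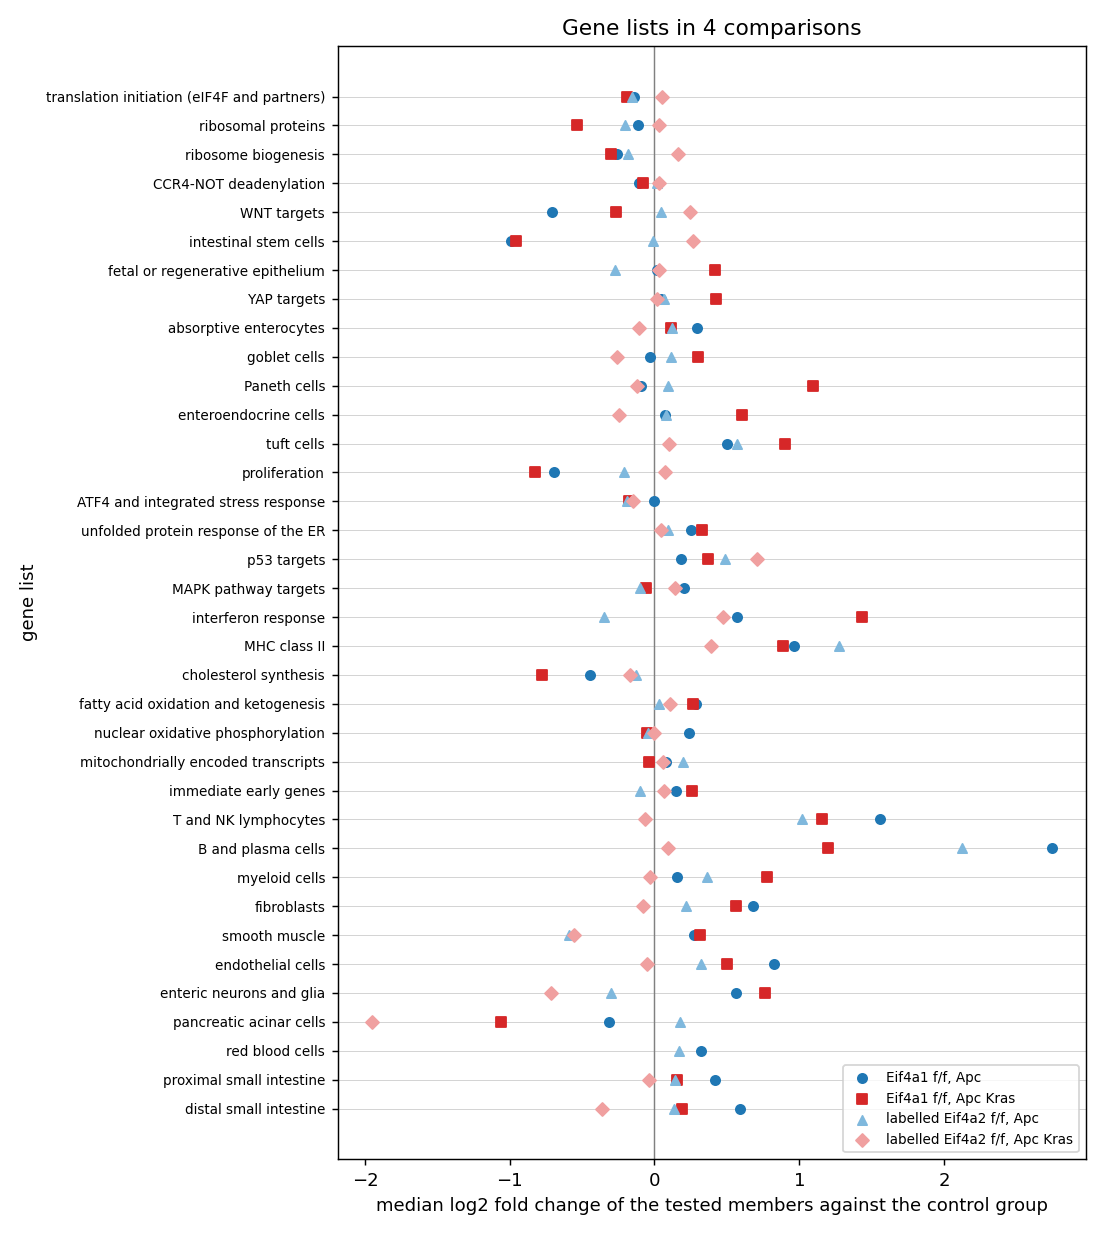
Median log2 fold change of the tested members of each gene list (vertical axis) against the control group (horizontal axis), in the 4 comparisons marked by colour and shape. With Eif4a1 deletion the proliferation list had medians of -0.697 in Apc and -0.824 in Apc Kras, and the interferon response list had 0.57 and 1.43.

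Genes responded in the same direction to Eif4a1 deletion in both backgrounds more often than independent lists would give. Among 19230 genes tested in both, 372 rose in both (99.3 for independent lists) and 573 fell in both (125 for independent lists), while 3 went opposite ways. Gkn3 fell and Krt12 rose in each, as did Eif4a2. Of the genes called in both, 54 besides Eif4a1 lay within 20 Mb of it on chromosome 11, and 53 of these changed in the same direction. Nearly all genes called in both did so, which leaves the near genes no different in this. How many would lie there by chance was not worked out. Krt12 lies farther away on that chromosome (99415666 to 99422259). Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.628 and a Spearman correlation of 0.666, and 75.5% had the same sign. With smooth muscle and B cell list levels as covariates, a choice made after seeing the data, the Pearson correlation was 0.3. Nlrp1b, an inflammasome sensor gene close to Eif4a1 on chromosome 11 (71153102 to 71230733), fell to 1.61 from 13.1 CPM in Apc and to 1.51 from 8.79 CPM in Apc Kras (log2 -3.02 ± 0.19 and -2.48 ± 0.26). It was chosen after its values were seen.

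The effect of Eif4a1 deletion was not shown to differ between backgrounds for any gene. The edgeR test of the difference called 0 of 20958 genes, with 2267 at an unadjusted p under 0.05 (1048 by chance), while DESeq2 called 147 and limma-voom 7. The smallest adjusted p was 0.0546, for Prox1 (log2 difference 2.55) and Plgrkt (-1.20), both chosen after their values were seen. Differences in the named lists between backgrounds were not tested as such. Without Apc Kras replicate 1 the count was 281.

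**Figure D3:**
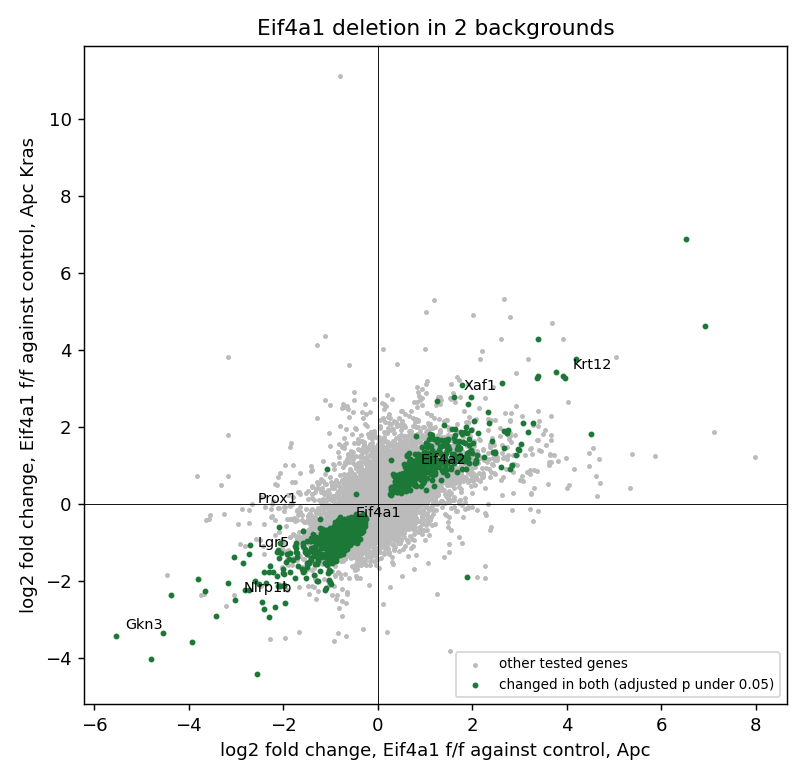
Log2 fold change of each gene with Eif4a1 deletion in Apc (horizontal axis) against that in Apc Kras (vertical axis), with genes changed in both in green and other tested genes in grey. Of the green genes 372 rose in both, 573 fell in both and 3 went opposite ways.

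In the Apc background, the libraries labelled Eif4a2 f/f differed from the controls in 3 genes, although Eif4a2 counts were not lower. Clec16a, a regulator of mitophagy on chromosome 16 (10545339 to 10744878) within 20 Mb of Eif4a2, rose to 56.3 ± 2.71 from 30.5 ± 2.36 CPM (log2 0.91 ± 0.08, edgeR adjusted p = 0.00329), and 4 of 4 libraries lay above the controls. Rpl22l1, a paralog of the ribosomal protein gene Rpl22, fell to 44.1 ± 4.51 from 79.8 ± 7.91 CPM (log2 -0.83 ± 0.09, edgeR adjusted p = 0.0191). Its pseudogene copy Gm15421, which matches it at up to 100% identity over 79.9% of the copy and was chosen after its values were seen, fell with it (log2 -1.11). The Rpl22l1 and Gm15421 values are uncertain because they share reads, and the Rpl22l1 call was lost without each of Apc replicates 1, 2, 3 and 4 and Apc Eif4a2 replicates 1, 3 and 4 (log2 -0.77 to -0.89). Of 20061 genes 1469 had an unadjusted p under 0.05, and DESeq2 called 44. With only the 2 groups compared no gene was called, Clec16a included.

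Camera called 19 lists in this comparison, while no member of any of them passed over all genes. The 8 MHC class II genes were higher by a median of 1.27 on the log2 scale (7 adjusted over the list alone), with H2-DMb1 at 1.26 ± 0.24 (uncertain because of its copy) and H2-Aa at 1.46 ± 0.31 (camera adjusted p = 1.72e-10, and adjusted p = 0.376 with an estimated correlation). Without Apc Eif4a2 replicate 2 the MHC class II median was 1.23 and no member passed adjusted over the list alone. T and NK lymphocyte genes had a median of 1.02 (8 of 22 adjusted over the list alone), with Klrd1 and Cd8a each at 0.80, and B and plasma cell genes a median of 2.12 (1 of 16 adjusted over the list alone), with Jchain at 0.92 and Mzb1 at 1.19 (uncertain because of an overlapping gene). Camera returned adjusted p = 3.65e-11 and 5.92e-07 for these, and adjusted p = 0.469 and adjusted p = 0.474 with an estimated correlation. Ighm stood at 385 CPM in Apc Eif4a2 replicate 2, against 10.1 to 19.9 CPM in the other 3 libraries. Without that library the medians were 0.81 for T and NK lymphocytes and 0.69 for B and plasma cells, with no member past the threshold over the list alone. Tuft cell genes (Hck 0.65, Alox5ap 0.68) and p53 targets (Dglucy 0.91, Aen 0.64) had medians of 0.57 and 0.49, with none past the threshold over the list alone. The camera test gave adjusted p = 1.43e-05 and 1.79e-08 for these, and adjusted p = 0.469 with an estimated correlation for both. Myeloid genes (Itgax 0.42, Cx3cr1 0.49) and mitochondrially encoded transcripts (mt-Nd4l 0.38 and mt-Nd5 0.26, both uncertain because of nuclear copies) had medians of 0.36 and 0.20. Testing with camera gave adjusted p = 0.0344 and 0.0143, and adjusted p = 0.827 and adjusted p = 0.784 with an estimated correlation.

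Lists with lower medians included ribosomal proteins (-0.20, Rps2 -0.38 and Rpl19 -0.37, both uncertain because of copies), ribosome biogenesis (-0.18, Nhp2 -0.43 and Polr1c -0.29) and translation initiation (-0.16, Eif4ebp1 -0.66 and Eif4e -0.28). Camera gave adjusted p = 7.66e-27, 1.75e-10 and 7.41e-09 for them, and adjusted p = 0.376, adjusted p = 0.724 and adjusted p = 0.433 with an estimated correlation. Proliferation (-0.21, Birc5 and Cdk1 each -0.40), the ATF4 response (-0.19, Chac1 -1.11 and Psph -0.44) and smooth muscle (-0.59, Hspb7 -1.24 and Actg2 -1.11) were lower as well. Camera returned adjusted p = 1.74e-06, 1.19e-05 and 5.23e-07 for them, and adjusted p = 0.784, adjusted p = 0.376 and adjusted p = 0.64 with an estimated correlation. Cholesterol synthesis (-0.13, Pmvk -0.32 and Acat2 -0.37), enteric neurons and glia (-0.30, Plp1 0.35 and Chrm2 -0.72), fetal or regenerative epithelium (-0.28, Msln -2.89 and Tnfaip2 0.38) and immediate early genes (-0.10, Klf6 -0.25 and Ier5 0.33) had camera adjusted p = 0.00277, 0.00475, 0.0183 and 0.0409, and adjusted p = 0.784 with an estimated correlation for each. Interferon response genes (-0.35, Ifit1bl1 -1.22 and Nlrc5 0.79) and nuclear oxidative phosphorylation genes (-0.04, Ndufc2 -0.18 and Ndufs2 -0.15) had camera adjusted p = 0.0143 and 0.0218, and adjusted p = 0.918 with an estimated correlation for both. None of the members of these lower lists passed adjusted over the list alone. As many as 19 lists were called in 9 of 35 splits of the libraries, another split gave 191 genes against the 3, and the interferon list pointed higher without Apc replicate 2 (camera adjusted p = 0.394).

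Calls of some of these lists rested on single libraries, as the camera adjusted p without them shows. Without Apc replicate 1 the myeloid call was lost (0.199). Without replicate 2 it was those of enteric neurons and glia (0.215), fetal or regenerative epithelium (0.544), immediate early genes (0.8) and mitochondrially encoded transcripts (0.0895). Without replicate 3 the interferon response (0.211) and mitochondrially encoded transcripts (0.0978) lost theirs, and without replicate 4 it was those of cholesterol synthesis (0.2) and myeloid cells (0.592). Among the libraries labelled Eif4a2 f/f, calls lost without replicate 1 were enteric neurons and glia (0.187) and the interferon response (0.0535). Those lost without replicate 2 were fetal or regenerative epithelium (0.111), immediate early genes (0.0693), the interferon response (0.0534), myeloid cells (0.0716) and nuclear oxidative phosphorylation (0.306). Without replicate 3 they were enteric neurons and glia (0.0932), fetal or regenerative epithelium (0.383), immediate early genes (0.238), the interferon response (0.73) and mitochondrially encoded transcripts (0.516). Replicate 4 carried the calls of cholesterol synthesis (0.121), myeloid cells (0.653) and nuclear oxidative phosphorylation (0.376).

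In Apc Kras, 6 genes differed in the libraries labelled Eif4a2 f/f, again with Eif4a2 counts not lower. C87414 rose by 2.63 ± 0.33 on the log2 scale (edgeR adjusted p = 0.0266, uncertain because of its copies), the phospholipase gene Pla2g4c by 1.67 ± 0.17 (11.5 ± 1.45 against 3.52 ± 0.65 CPM, edgeR adjusted p = 0.00499), and Rpl34, a ribosomal protein gene on chromosome 3 (130726831 to 130730398), by 0.61 ± 0.07 (163 ± 7.06 against 108 ± 4.73 CPM, edgeR adjusted p = 0.00887). Arhgap31, a GTPase-activating protein gene on chromosome 16 (38598340 to 38713274) within 20 Mb of Eif4a2, fell by 1.28 ± 0.18 (edgeR adjusted p = 0.0387), and Gm2999 and Gm24616 were the other 2 that fell. Of 19703 genes, 1739 had an unadjusted p under 0.05. DESeq2 called 140, there were 13 with no filter and 25 with smooth muscle and B cell list levels as covariates (a choice made after seeing the data). With only the 2 groups compared none was called. The Arhgap31 call was lost without any single library among Apc Kras replicates 1 and 2 and Apc Kras Eif4a2 replicates 1 to 4 (log2 -1.18 to -1.38).

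Camera called 12 lists here. The 30 p53 targets had a median log2 fold change of 0.71, with none past the threshold over all genes and 19 higher adjusted over the list alone, among them Dglucy (0.91 ± 0.20) and Rps27l (0.61 ± 0.14) (camera adjusted p = 1.36e-12, and adjusted p = 0.945 with an estimated correlation). In the ribosomal protein list Rpl34 rose, 2 members passed adjusted over the list alone, and Rps3a1 stood at 0.54 (uncertain because of copies). Ribosome biogenesis (median 0.16, Polr1e 0.31 and Nop2 0.25), WNT targets (0.25, Notum 0.63 and Ccnd1 0.75, both uncertain because of overlapping genes), stem cells (0.27, Igfbp4 0.51 and Ascl2 0.61) and interferon response (0.47, Bst2 0.98 and Ifi27 0.51) were higher, with no member past the threshold either way. The camera test gave adjusted p = 0.0427 for the ribosomal protein list and 1.34e-05, 0.0219, 0.0219 and 0.00986 for these 4, and adjusted p = 0.945 with an estimated correlation for each. Goblet cells (-0.26, Ern2 -0.82 and Creb3l1 -0.45) and enteroendocrine cells (-0.24, Insm1 -1.39 and Rfx6 -0.86) were lower, with 1 member each past the threshold over the list alone. Testing with camera gave adjusted p = 0.00221 and 0.00791, and adjusted p = 0.945 with an estimated correlation for both. The ATF4 response (-0.15, Sesn2 1.23 and Vldlr -0.88), cholesterol synthesis (-0.17, Lss -0.36 and Ldlr -0.34), smooth muscle (-0.56, Hspb6 -1.05 and Smtn -0.35) and enteric neurons and glia (-0.71, Ret -0.66 and S100b 0.86) were lower with none past either threshold. Camera gave adjusted p = 0.0219, 0.000283, 0.0322 and 0.00203, and adjusted p = 0.945 with an estimated correlation for each.

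The pancreatic protease gene Prss2 reached 26.4 CPM in Apc Kras replicate 2, and without replicates 1 and 2 of the controls no gene was called. As many as 12 lists were called in 33 of 35 splits, 65 genes were called in another split, and without Apc Kras replicate 1 the ribosomal protein and ribosome biogenesis lists pointed lower (camera adjusted p = 1.19e-07 and 0.462). Without replicates 1 and 2 together, a choice made after seeing the data, the directions of ribosomal proteins (2.89e-07), WNT targets (0.827), stem cells (0.712) and the ATF4 response (0.921) turned. Without Apc Kras replicate 1 the calls of WNT targets, stem cells and goblet cells (camera adjusted p = 0.85 for each), enteroendocrine cells (0.923, pointing higher), enteric neurons and glia (0.388) and smooth muscle (0.853) were lost. Enterocytes and proliferation then came to be called in the other direction (0.00103 for both). Without Apc Kras replicate 2 the calls of the ATF4 response (0.809, pointing higher) and the interferon response (0.552) were lost. Without replicate 3 it was those of the interferon response (0.0658) and smooth muscle (0.138), and without replicate 4 that of smooth muscle (0.0896). Among the libraries labelled Eif4a2 f/f, calls lost without replicate 1 were stem cells (0.0673) and ribosomal proteins (0.213), and without replicate 2 the interferon response (0.207) and smooth muscle (0.371). WNT targets (0.0847), the ATF4 response (0.146) and the interferon response (0.685) were not called without replicate 3. Stem cells and ribosomal proteins (0.167 for both) and smooth muscle (0.345) were not called without replicate 4.

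Effects of the libraries labelled Eif4a2 f/f differed between backgrounds for 1 gene. Rpl34 had a difference of log2 fold changes of 0.83 ± 0.10 (edgeR adjusted p = 0.00101), and 1515 of 20958 genes had an unadjusted p under 0.05. The effects in the backgrounds had a Pearson correlation of 0.132 and a Spearman correlation of 0.069 across genes, 49.8% had the same sign, and no gene was called in both. The Pearson value was 0.294 without Apc Kras replicate 1, 0.036 without replicate 2 and 0.055 without Apc Kras Eif4a2 replicate 2. It was 0.223 without Apc Kras replicates 1 and 2 together and 0.218 with smooth muscle and B cell list levels as covariates, both choices made after seeing the data, and 0.206 with limma-voom.

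Set directly against the libraries labelled Eif4a2 f/f of the same background, Eif4a1 deletion raised Krt12 and lowered Gkn3 in both backgrounds, with Eif4a2 counts not lower in the reference libraries. In Apc, Krt12 (log2 3.83 ± 0.28), the phosphate transporter gene Slc34a2 (2.62 ± 0.46), Bbox1 (2.42), the activin antagonist follistatin (Fst, 2.14 ± 0.40) and Dab1 (2.11 ± 0.24) were highest. Gkn3 (-5.93 ± 0.55), Egfl6 (-4.44), Aqp5 (-4.05), Pla2g4c (-3.92) and Nlrp1b (-3.50 ± 0.20) were lowest. In Apc Kras, the aryl hydrocarbon receptor target Cyp1a1 (6.33 ± 1.23), Krt12 (4.46 ± 0.57), Dgkb (3.27), Ptn (3.19) and Adamtsl3 (3.01) were highest, and Gkn3 (-4.97 ± 0.72), Pck1 (-3.62), S100g (-3.56), Eif4ebp3 (-3.48) and Aqp5 (-3.23) lowest. Counts of changed genes by edgeR were 1009 in Apc (321 higher, 688 lower) and 5616 in Apc Kras (2793 higher, 2823 lower). Myh11, the myosin heavy chain gene of smooth muscle, stood at 416 to 572 CPM in Apc Kras Eif4a1 and at 83.0 to 300 CPM in the Apc Kras libraries labelled Eif4a2 f/f. With smooth muscle and B cell list levels as covariates, a choice made after seeing the data, the counts were 296 in Apc and 35 in Apc Kras. Ptn in Apc Kras turned to a log2 value of -0.13 in that fit. In Apc there were 669 with no filter, 2115 with DESeq2, 1826 in 1 fit of 24 libraries and 373 with only the 2 groups. In fits chosen after seeing the data there were 450 without the 2 immunoglobulin-high libraries and 661 without Apc Eif4a1 replicates 1 and 2. With upper-quartile scaling the Apc Kras split became 3316 higher and 2151 lower. The Apc count was 284 without Apc Eif4a2 replicate 3, 356 without replicate 1 and 515 without replicate 2, and 632 and 628 without Apc Eif4a1 replicates 2 and 4, and the Apc Kras count was 1704 without Apc Kras Eif4a1 replicate 2 and 3463 and 3457 without Apc Kras Eif4a2 replicates 2 and 4.

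Eif4a1 deletion and the libraries labelled Eif4a2 f/f, in which Eif4a2 counts were not lower, were also compared through their differences from the same controls, which share chance values. In Apc the effects had a Pearson correlation of 0.542 and a Spearman correlation of 0.411 across genes, where unchanged groups simulated against those controls gave mean values of 0.498 and 0.461. The same sign was seen in 64.3% of genes, against 66.6% simulated, so the Spearman correlation and the sign were below the simulated values. The simulated groups had no effect, so values below theirs do not tell whether the real effects were alike. Leaving out 1 library at a time gave the Pearson correlation a standard error of 0.287 in Apc and 0.373 in Apc Kras. The covariance was 0.162 against 0.0599 simulated, a difference of 0.102, and with the controls split between the comparisons the correlation averaged 0.288 (0.125 to 0.462 over 6 ways). The Pearson correlation was 0.348 without Apc Eif4a2 replicate 2, and, in fits chosen after seeing the data, 0.306 without the 2 immunoglobulin-high libraries (Apc Eif4a1 replicate 1 and Apc Eif4a2 replicate 2) and 0.324 without Apc Eif4a1 replicates 1 and 2. In Apc Kras the Pearson correlation was 0.183 against 0.436 simulated, the Spearman correlation 0.0788 against 0.401, the covariance 0.05 against 0.0434, and with split controls the correlation averaged 0.00318 (-0.281 to 0.297). The Pearson value there rested on single libraries: it was 0.512 without Apc Kras replicate 1, 0.121 without Apc Kras Eif4a1 replicate 2, and 0.049 and 0.086 without Apc Kras Eif4a2 replicates 2 and 3. In fits chosen after seeing the data it was 0.476 without Apc Kras replicates 1 and 2 and 0.576 with smooth muscle and B cell list levels as covariates. Clec16a was called higher in both comparisons in Apc. In Apc Kras 1 gene was called higher in both, C87414, and 1 gene, Gm2999, in opposite directions.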

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

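Apart from the camera tests of lists and the test of the difference between backgrounds, which were planned, the tests in this part were chosen only after the results they bear on had been seen.

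Chance in how libraries were grouped is argued against for the gene counts of Eif4a1 deletion. Only the real split, 1 of 35, gave as many as the 1695 in Apc (highest other 2) and as the 5273 in Apc Kras (highest other 3468), which is the smallest share 35 splits can give. The same holds for Eif4a1 deletion against the libraries labelled Eif4a2 f/f, with 1 of 35 splits for 1009 genes in Apc (highest other 3) and 1 of 35 for 5616 in Apc Kras (highest other 2). The split with 3468 genes put Apc Kras replicate 1 with Apc Kras Eif4a1 replicates 2, 3 and 4, so a split that mixes the groups can also call many genes there. Chance cannot be excluded for the counts of 3 genes in the libraries labelled Eif4a2 f/f in Apc (2 of 35 splits, highest other 191) or 6 in Apc Kras (2 of 35, highest other 65). These splits compare numbers of calls only and do not test single genes such as Gm2999 and Gm24616, which are among the 6. The splits with 191 and 65 genes exchanged Apc replicate 4 with Apc Eif4a2 replicate 4 and Apc Kras replicate 2 with Apc Kras Eif4a2 replicate 3, and call several times the real counts, which points to a structure of the samples. Both part the libraries by Myh11 of smooth muscle without overlap (at least 464 against at most 318 CPM, and at least 300 against at most 175 CPM), though whether smooth muscle is its source was not tested. Chance cannot be excluded for the 1 gene that differed between backgrounds in the libraries labelled Eif4a2 f/f (4 of 60 drawn splits, highest other 1). For Eif4a1 deletion 0 genes differed, which all 60 of 60 drawn splits reach by necessity, so they decide nothing about chance (highest other 616, which may also mark a structure of the samples). For counts of lists it cannot be excluded in any comparison: 18 lists in Apc with Eif4a1 deletion (15 of 35, highest other 25), 21 in Apc Kras (11 of 35, highest other 24), 19 in Apc with the libraries labelled Eif4a2 f/f (9 of 35, highest other 21) and 12 in Apc Kras (33 of 35, highest other 22).

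Shares of genes with changes near the floxed genes were above those of most windows of as many genes on other chromosomes, except for the called genes of Apc Kras. Neighbouring windows shared most of their genes, so the numbers of windows are not numbers of separate comparisons. In Apc, 12.4% of genes within 20 Mb of Eif4a1 were called, above each of 46 windows (highest 10.9), and 12.1% at 5 to 20 Mb (1 of 87 windows as high, at 12.35). The share near Eif4a2, not floxed in this comparison, was 11.48% and also above those 46 windows, though over fewer genes (392 against 663). The windows therefore cannot mark the called genes as tied to the floxed locus. A response unrelated to position, an effect of the deletion on its neighbours alone and DNA of another strain carried with the floxed allele all stay open for them. In Apc Kras called genes did not gather near Eif4a1 (27.0% and 24.6%, with 27.86% near Eif4a2). Among the 100 genes with the smallest p, a measure added when the called genes of Apc Kras showed no gathering, the shares within 20 Mb were 2.56% (Apc) and 1.69% (Apc Kras) for Eif4a1 and 2.55% and 1.56% for Eif4a2, at 5 to 20 Mb 2.47%, 1.26%, 2.79% and 1.79%, and near the gene that was not floxed 0.51%, 0.52%, 0.45% and 0.62%. In Apc the shares near both floxed genes were above every window, which DNA of another strain around the floxed alleles may account for. For Eif4a2 in Apc Kras, 5 of 132 windows were as high within 20 Mb (highest 2.34) and 6 of 208 at 5 to 20 Mb (highest 2.87). For Eif4a1 in Apc Kras no window was as high within 20 Mb (highest 1.23), and 5 of 87 were at 5 to 20 Mb. As the windows overlapped, the Apc Kras numbers do not tell such DNA from a local effect for Eif4a1. For Eif4a2 in Apc Kras they do not tell it from a response unrelated to position either. A response of these genes to the loss of the helicase stays open as the biological explanation.

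Eif4a2 counts were not lower in the libraries labelled Eif4a2 f/f. A wrong label is argued against by Gm2999 and by Gm24616, each below every control of its background in 8 of 8 libraries. Both were chosen after their values were seen. Sequence differences in DNA of another strain around the floxed allele could also lower them, so these counts do not exclude a lack of recombination. A deletion of part of the gene that leaves the other exons in the transcript may account for Eif4a2 counts that were not lower. Gm2999, whose sequence matches exons 8 to 11, had log2 fold changes of 0.55 (Apc) and 0.84 (Apc Kras) with Eif4a1 deletion. Whole-gene Eif4a2 counts had 0.71 and 0.85 there, so Gm2999 followed them where Eif4a2 was not floxed. Gm24616, however, stood at 0.421 against 0.557 CPM with Eif4a1 deletion in Apc and at 0.617 against 0.518 CPM in Apc Kras. Which exons were removed, and reads of exons 8 to 11 in Eif4a2 itself, were not measured, since the counts are per gene.

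Of 7 lists of immune and stromal cells, camera placed 5 higher with Eif4a1 deletion in Apc, without myeloid cells and smooth muscle (adjusted p = 0.424 and 0.294), and 6 in Apc Kras, without smooth muscle (adjusted p = 0.0924). A lower share of epithelium alone, which would raise all of them alike, is argued against in Apc by the spread of the 7 lists, from 0.17 (myeloid) to 1.91 (B and plasma cells) on the log2 scale (exact permutation p = 0.0286 over 70 splits, the smallest they can give). The spread was not tested again without Apc Eif4a1 replicate 1 (Ighm at 996 CPM), so a lower share together with follicle tissue in that library is not argued against. In Apc Kras a lower share cannot be told apart (p = 0.6857, exact permutation). Lymphoid follicle tissue in single libraries is argued against as the whole cause in Apc, since medians without the 2 libraries with high immunoglobulin counts were 1.08 for T and NK cells and 1.67 for B and plasma cells, and 18 of 22 and 12 of 16 members stood above every control in each of the 3 Apc Eif4a1 libraries left. Those medians still hold Apc Eif4a1 replicate 2, where Ighm stood at 36.75 CPM against 10.9 to 13.8 CPM in the controls. A change in the immune cells after the deletion stays open as the biological explanation, as does a lower epithelial share in Apc Kras, and in Apc that share together with follicle tissue.

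Of 419 groups of 4 libraries examined, 37 held a library whose gap to the nearest of the others took more of the range than Dixon's critical value, where chance gives about 1 in 20, or 20.9. In Apc Kras replicate 1 there were 11, given as the gap over the range: Krt12 0.873, Art2b 0.901, Apol9b 0.8299, Ifi27 0.892, Ighm 0.866 and Notum 0.865 were highest there, and Rpl3 0.836, Rpl36a 0.906, Polr1c 0.894, Cdca7 0.831 and Ddb2 0.953 were lowest. In Apc Eif4a1 replicate 1, Cd6 (0.896), Cd3d (0.849) and Prr18 (0.89) were highest and Nlrp1b (0.885) lowest. In Apc Eif4a1 replicate 2, Rpl19 (0.86), Tnfrsf17 (0.921) and Fst (0.955) were highest, in replicate 3 Aqp5 was lowest (0.868), and in replicate 4 Acadm was highest (0.839). Among the Apc controls, Egfl6 (0.879) and Aldob (0.867) were highest and Nhp2 (0.877) lowest in replicate 4, and Ier5 (0.836) was highest in replicate 2. Among the Apc libraries labelled Eif4a2 f/f, the percent of counts in protein-coding genes (0.952) and Pla2g4c (0.847) were highest in replicate 1, Eif4a2 (0.8294) and Mzb1 (0.978) were highest in replicate 2, and Polr1c (0.887) was lowest in replicate 4. Among the Apc Kras controls Ccnb1ip1 was highest in replicate 3 (1.0, from 1 count) and Rfx6 lowest in replicate 2 (0.904). With Eif4a1 deletion in Apc Kras, Mt2 was lowest in replicate 2 (0.872) and Adamtsl3 highest in replicate 4 (0.859). Among the Apc Kras libraries labelled Eif4a2 f/f, protein-coding counts were lowest (0.933) and Rfx6 highest (0.867) in replicate 1, Igfbp4 lowest in replicate 2 (0.87) and Cyp1a1 highest in replicate 3 (0.892). Rpl34 differed between backgrounds in the libraries labelled Eif4a2 f/f, by a log2 difference of 0.834 in the test of the difference itself. The gaps of Eif4a2 and Apol9b lay closest to the critical value.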

How the results depend on the processing

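Fits without the immunoglobulin-high libraries, without Apc Eif4a1 replicates 1 and 2, without Apc Kras replicates 1 and 2, and with cell type covariates were chosen after seeing the data; other settings were planned. Values are counts of genes called unless stated, and the cause was not tested. For Eif4a1 deletion in Apc (1695) there were 1116 with no filter, 3170 with DESeq2, 452 with covariates, 889 without the immunoglobulin-high libraries, 431 without Apc Eif4a1 replicates 1 and 2, 3254 in 1 fit of 24 libraries and 540 with only the 2 groups. In Apc Kras (5273) there were 22 with covariates and 3380 with only the 2 groups. For the libraries labelled Eif4a2 f/f in Apc (3) there were 44 with DESeq2 and 0 with only the 2 groups, and in Apc Kras (6) 13 with no filter, 140 with DESeq2, 25 with covariates, 0 without Apc Kras replicates 1 and 2 and 0 with only the 2 groups. Between Eif4a1 deletion and the libraries labelled Eif4a2 f/f in Apc (1009) there were 669 with no filter, 2115 with DESeq2, 296 with covariates, 450 without the immunoglobulin-high libraries, 661 without Apc Eif4a1 replicates 1 and 2, 1826 in 1 fit and 373 with only the 2 groups, and in Apc Kras (5616) 35 with covariates. For the difference of Eif4a1 effects between backgrounds (0) there were 3 without sex, 2 with RLE scaling, 2 with no filter, 5 at a mean CPM of 2, 147 with DESeq2, 7 with limma-voom, 5 with covariates and 1 without the immunoglobulin-high libraries, and for the libraries labelled Eif4a2 f/f (1) 14 with DESeq2.

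Replicate numbers did not pair the libraries: 2 of 12 pairs in Apc and 3 of 12 in Apc Kras had a correlation of deviations over 0.1 (-0.467 to 0.241 and -0.27 to 0.339), and in 3 and 7 of 24 comparisons of a library with another group its own number correlated best. With the replicate block there were 527 genes for Eif4a1 deletion in Apc, 0 for the libraries labelled Eif4a2 f/f, 333 between these and Eif4a1 deletion and 1 for the difference of Eif4a1 effects, and of named genes 67 were no longer past the threshold and 4 came past it.

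Lists called with an estimated correlation were 0, 0, 0 and 0 in place of 18, 19, 21 and 12, and with fry 6, 0, 12 (CCR4-NOT among them, which camera did not call) and 0; without Apc Eif4a1 replicates 1 and 2 there were 10. The correlation of the effects of both groups in Apc Kras was 0.576 with covariates, and that of Eif4a1 effects between backgrounds 0.3 with covariates and 0.537 without Apc Eif4a1 replicates 1 and 2. Leaving out 1 library at a time gave 402 to 2364 genes for Eif4a1 deletion in Apc and 2055 to 8739 in Apc Kras, 1 to 4 and 2 to 9 for the libraries labelled Eif4a2 f/f, 284 to 987 and 1704 to 5273 between these and Eif4a1 deletion, and 0 to 281 and 1 to 1 for the differences between backgrounds. It gave 18 to 22, 14 to 20, 18 to 23 and 10 to 16 lists, and correlations of 0.348 to 0.674 (Apc) and 0.049 to 0.512 (Apc Kras) between both groups and 0.58 to 0.639 (Eif4a1) and 0.036 to 0.294 (libraries labelled Eif4a2 f/f) between backgrounds. In Apc the 3 genes became 1 without any of Apc replicates 1 to 4 or Apc Eif4a2 replicates 1 or 3, and in Apc Kras the 6 became 2 without Apc Kras Eif4a2 replicate 4.

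Lists that turned direction are given with their camera adjusted p there: ribosome biogenesis with Eif4a1 deletion in Apc without Apc Eif4a1 replicates 1 and 2 (0.49), and for the libraries labelled Eif4a2 f/f the interferon list without Apc replicate 2 (0.394), ribosomal proteins (1.19e-07), ribosome biogenesis (0.462), enterocytes (0.00103), enteroendocrine cells (0.923) and proliferation (0.00103) without Apc Kras replicate 1, the ATF4 list without Apc Kras replicate 2 (0.809), and ribosomal proteins (2.89e-07), WNT targets (0.827), stem cells (0.712), Paneth cells (0.01) and the ATF4 list (0.921) without both. Leaving out 1 library at a time, the adjusted p of these lists reached from 1.01e-08 to 0.00419 (ribosome biogenesis in Apc), 2.95e-07 to 0.73 (interferon), 1.19e-07 to 0.213 (ribosomal proteins), 6.02e-16 to 0.462 (ribosome biogenesis in Apc Kras), 0.00103 to 0.987 (enterocytes), 2.44e-05 to 0.923 (enteroendocrine cells), 2.81e-05 to 0.621 (proliferation), 0.000547 to 0.809 (the ATF4 list), 0.000346 to 0.85 (WNT targets), 2.37e-06 to 0.85 (stem cells) and 0.228 to 0.996 (Paneth cells). Genes that turned with covariates were Rcl1 (log2 0.0408), Nop16 (0.0965), Fabp1 (-0.138) and Cd79a (-0.336) with Eif4a1 deletion in Apc Kras and Ptn (-0.125) against the libraries labelled Eif4a2 f/f there. Of the named gene results, 506 kept direction and side of the threshold with RLE scaling, 500 with upper-quartile scaling, 488 with limma-voom, 466 with DESeq2, 479 without sex and 313 with covariates, and 188 were weaker with covariates; leaving out 1 library kept 3644 and weakened 449. The comparisons with wild-type samples were not run. Depth (25642265 to 39668451 counts) limits the lowest genes, such as Gm24616 below 1 CPM.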

Other observations

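With Eif4a1 deletion in Apc, none of 20 goblet cell genes and none of 17 Paneth cell genes passed (medians -0.034 and -0.094, camera adjusted p = 0.533 and 0.219), and of 25 enteroendocrine genes 3 rose (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.818). In Apc Kras, 3 goblet cell genes rose and 2 fell of 19 (4 and 2 adjusted over the list alone, camera adjusted p = 0.239), and 3 of 35 enterocyte genes rose while 1 fell (camera adjusted p = 0.239). Markers of the proximal and of the distal small intestine had medians of 0.416 and 0.588 in Apc and 0.158 and 0.193 in Apc Kras, and camera called neither (adjusted p = 0.0831 and 0.19 in Apc, 0.251 and 0.691 in Apc Kras).

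The ATF4 and integrated stress response list, which follows phosphorylation of eIF2, was not called with Eif4a1 deletion. In Apc 3 of its 34 members rose and 3 fell, and in Apc Kras 1 rose and 4 fell (camera adjusted p = 0.831 and 0.239). Targets of the MAPK pathway, 24 genes, had 1 riser and 1 faller in Apc and 2 risers in Apc Kras (camera adjusted p = 0.735 and 0.669). Of 19 genes of the CCR4-NOT deadenylation complex, which shortens mRNA poly(A) tails, 1 fell in Apc, and 1 rose and 6 fell in Apc Kras (camera adjusted p = 0.0536 and 0.0645). With fry the list was lower in Apc Kras (adjusted p = 0.0189) and not called in Apc (adjusted p = 0.147). In the libraries labelled Eif4a2 f/f none of the 19 passed in either background (medians 0.016 and 0.032, camera adjusted p = 0.811 and 0.847), although Eif4a2 counts were not lower there.

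Of the 39 count columns 15 matched no sample's description, and their values were not examined.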
